A study of Mus musculus with 5 samples.

How the data were processed

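The deposited table gave 1 RMA intensity per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes, and the version is not given in the sources used here. RMA as a method subtracts background, makes the arrays' distributions alike and combines the probes of a set. The values were on the linear scale, with array medians of 42.0 to 43.3, although log2 values had been assumed when the tests were chosen. Log2 was therefore taken here before every step, and the tests were kept.

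The table had 41345 probe sets on 5 arrays, and each of its sample columns was matched to a sample, with 0 unmatched. Of the probe sets, 23521 named 1 gene symbol, 1814 named several and 16010 were unnamed, including 190 control probe sets. Entrez identifiers of 23328 were found in the reference gene table and 193 were not, and 0 symbols changed. For 1082 genes with several probe sets the 1 with the highest mean over the arrays stood for the gene. In 5 of these genes, probe sets were called in opposite directions. This gave 22180 genes, all tested without a filter on dim values. A gene missing from the table was not analysed here.

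RMA values carry no detection call, so the background level was taken as the 95th percentile of 1405 probe sets of olfactory and vomeronasal receptor genes, log2 5.08 (33.8 on the linear scale). Between 14510 and 14597 genes per array lay above it. A log2 difference from a value under this level depends on background, and folds over background were taken from the level itself. A further property of the table was that 5385 genes had the same value, within 1e-06 on the log2 scale, on 3 or more arrays, 601 of them on all 5, at a median level of 4.58. In 963 genes both the iPSC pair and the iNSC pair were identical.

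Groups were iPSC (n = 2), brain NSC (n = 1) and iNSC (n = 2), as read from the labels. Each array came from a separate line, and nothing in the labels says that lines were cultured independently, so p-values measure the spread between these samples, which may be partly technical. The small number of arrays limits the precision of every estimate. Genes were tested with limma 3.58.1 in R 4.3.3, in 1 model with 3 groups on all 5 arrays (2 residual degrees of freedom, prior degrees of freedom 0.774) and with Benjamini-Hochberg adjustment over all genes. The threshold was adjusted p under 0.05. The residual spread came only from both line pairs, and the brain NSC array was assumed to vary like them. Both cassettes are in the iNSC group, so cassette and line could not be separated. By Xist and Y-linked genes the iNSC lines also differed in sex, which could not be separated from cassette or line and enters the spread of that group. OKSM and BKSM lines, and iPSC clones 2 and 7, were compared without a test.

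Tests, alternatives, 30 gene lists and the rule for named genes were chosen before the data were examined. The rule named, for each tested comparison, the 10 genes with the largest rise and the 10 with the largest decrease among those with adjusted p under 0.05, non-overlapping groups and a brighter mean above background. Predicted, receptor and small RNA genes were skipped. For the pair of iNSC lines it named the 10 largest differences in each direction, and members of the lists were also open to be named, with the reprogramming factors always named. The lists had 588 different genes, of which 542 were measured and 46 were not.

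Each list was tested in each comparison with camera from limma, with a preset correlation of 0.01 and adjustment over lists. Counts of members that passed were taken over all genes and again with p-values adjusted over the list alone. Camera with a correlation estimated from the data and fry were alternatives. The estimated correlation rests on the 2 residual degrees of freedom, and 0 of the 90 list tests passed with it. Lists with an estimate under the preset, such as neural stem cell (0.00754) and epithelial genes (−0.0493), did not pass either. Not passing with it therefore does not tell whether correlation between genes explains a list. Where the estimate was high, such correlation stays a possible account of the camera call. Cell cycle (0.963), fibroblast and mesenchyme (0.907) and cholesterol and fatty acid synthesis genes (0.585) were such lists. For pairs of single arrays the list median was placed among 10000 random lists of the same size and similar intensity, as a description. For the comparisons that share arrays, 100 simulated data sets without group differences gave the overlap, correlation and position that shared arrays alone produce.

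The code was tested on simulated data with 22180 genes and 100 planted changes in 5 draws. The noise was normal, independent between genes, alike on all arrays of a gene and without genes at the same value on several arrays. The rates below therefore check the code and do not measure the power of the tests on the real arrays. At a log2 difference of 1 it recovered a mean of 56.4 in iNSC against iPSC, 39 in brain NSC against iPSC and 41.2 in iNSC against brain NSC, and at a log2 difference of 3 it recovered 90.2, 85.2 and 87.6. Mean false calls were 6.6, 5.8 and 5.2. With 4590 planted changes of realistic size, 4447 (96.9%) were recovered with 225.8 false calls. Camera called a moved list in 5 of 5 draws and an unmoved list in 0 of 5. With independent genes this could not check the preset correlation of 0.01. In the real data the estimated correlation was 0.963 for cell cycle genes and 0.907 for fibroblast and mesenchyme genes. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.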

Results

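The series asked whether mouse cells converted towards a neural fate with pluripotency factors resemble neural stem cells taken from the brain. The deposited table held 5 expression arrays of total RNA, each from a separate cell line, with RMA intensities taken to log2 here. The 2 induced pluripotent stem cell (iPSC) lines were BKSM clones 2 and 7. The 2 induced neural stem cell (iNSC) lines came from cells with the OKSM cassette (Oct4, Klf4, Sox2 and c-Myc) and from cells with the BKSM cassette. The brain neural stem cell (NSC) line came from E13.5 embryonic brain and was the only 1 of its group. After probes were named and merged, 22180 genes were measured on all 5 arrays. Each group mean below is a log2 intensity given with SD and n = 2, and each brain NSC value comes from 1 array.

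The neural arrays were close to each other and far from the iPSC arrays. Across all genes the correlation was 0.997 between both iPSC clones, 0.983 between both iNSC lines, 0.982 between the OKSM iNSC line and brain NSC, and 0.979 between the BKSM iNSC line and brain NSC. Neural and iPSC arrays correlated at 0.901 to 0.911. Nanog, a core pluripotency factor, read 12.05 ± 0.08 (SD, n = 2) in iPSC, 6.03 in brain NSC and 6.31 ± 0.33 (SD, n = 2) in iNSC. Nes, the intermediate filament nestin of neural progenitors, read 7.64 ± 0.24, 11.04 and 10.97 ± 0.14 in the same order. Sox2, a factor of both cell states, was high everywhere, at 11.62 ± 0.04, 11.39 and 10.92 ± 0.25.

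**Figure D1:**
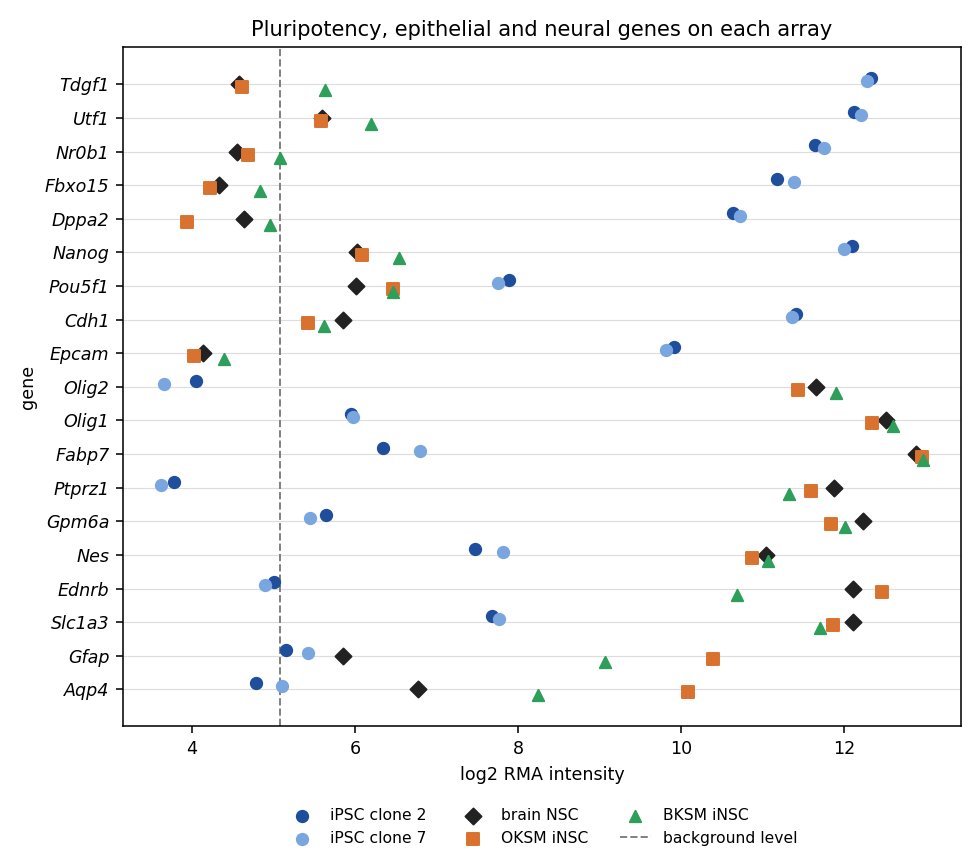
Log2 RMA intensity of 19 marker genes on each of the 5 arrays, 1 point per array. The dashed line marks the background level, log2 5.08.

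In iNSC against iPSC, genes of the pluripotent state fell and genes of neural progenitors rose. Olig2, a transcription factor of ventral neural progenitors and oligodendrocyte precursors (probe set 17327030), rose from 3.86 ± 0.28, under the background level of 5.08, to 11.67 ± 0.32 (SD, n = 2), at least 96.0-fold over background (limma adjusted p = 0.00836, and 0.0503 without the BKSM iNSC array). Ptprz1, a receptor phosphatase of radial glia (probe set 17456381), rose from 3.70 ± 0.11, also under background, to 11.46 ± 0.19, at least 83.3-fold over background (adjusted p = 0.00609). Tdgf1, which encodes the Nodal co-receptor Cripto of embryonic cells (probe set 17531685), fell from 12.31 ± 0.03 to 5.12 ± 0.72, which is near background (adjusted p = 0.0138). Nr0b1, a nuclear receptor of pluripotent cells, fell from 11.70 ± 0.08, 98.2-fold over background, to 4.88 ± 0.27, under background (adjusted p = 0.00719). With limma at adjusted p under 0.05, 2113 genes were higher and 2477 lower in iNSC, 20.7% of the 22180 tested, and 1273 and 1249 of them by at least 2-fold. The lowest adjusted p, 0.00609, was shared by 87 genes, among them Kitl, which encodes the KIT ligand, at a log2 difference of 5.38.

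The other genes named by rule on the higher side of this comparison were Cp (6.89, ceruloplasmin), Gpm6b (6.63), Ednrb (6.62), Olig1 (6.51), Timp4 (6.45), Fabp7 (6.39, the brain fatty acid binding protein of radial glia), Gpm6a (6.38) and Npas3 (6.10). On the lower side were Fbxo15 (−6.75), Utf1 (−6.27) and Dppa2 (−6.22), all markers of pluripotent cells. The zinc finger genes Zfp640 (−6.49) and Zfp981 (−6.45) were lower as well. Kcnma1 (−6.05), Zscan4e (−5.86, of the family active in 2-cell embryos) and Cdh1 (−5.86, E-cadherin) completed the list. With the mean of its probe sets Kcnma1 did not pass (−1.44, adjusted p = 0.0579). Timp4 and Fabp7 did not pass without the OKSM (adjusted p = 0.0672 and 0.0522) or the BKSM iNSC array (0.0697 and 0.0589). For 12 of the 20 genes named by rule the dimmer mean lay under background, so their log2 differences depend on values there.

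Of 32 measured pluripotency genes, 28 were lower in iNSC and 4 did not pass (30 lower when adjusted over the list alone). Their median log2 difference was −3.54 (camera adjusted p = 8.08e-16, and adjusted p = 0.195 with an estimated correlation). Zfp42 (−4.75), Dnmt3l (−4.44), Klf4 (−2.80) and Pou5f1 (−1.36) were among them. Of 33 neural stem cell genes, 25 were higher and 8 did not pass (27 higher over the list alone), with a median of 3.63 (camera adjusted p = 8.08e-16, and adjusted p = 0.195 with an estimated correlation). Sox9 rose by 4.54, Slc1a3 by 4.06, Hes5 by 3.62 and Pax6 by 1.70. Of 17 astrocyte genes, 11 were higher, among them Mlc1 (5.39), Gfap (4.43) and Aldh1l1 (3.23), and 6 did not pass (14 higher over the list alone). Their median was 1.95 (camera adjusted p = 4.67e-07, and adjusted p = 0.245 with an estimated correlation). Aqp4, the astrocyte water channel, did not pass at a difference of 4.22 (adjusted p = 0.0648).

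Epithelial genes were lower in iNSC: 14 of 20 passed and 6 did not (17 lower over the list alone), with a median of −2.36 (camera adjusted p = 1.06e-09, and adjusted p = 0.195 with an estimated correlation). Epcam fell by 5.66, Cldn6 by 4.14 and Krt8 by 2.71. Among 18 germline genes, 10 were lower, including Mael (−5.72), Ddx4 (−4.67) and Dazl (−3.90), and 8 did not pass (14 lower over the list alone). The germline median was −1.18 (camera adjusted p = 6.49e-07, and adjusted p = 0.424 with an estimated correlation). Of 13 epiblast and primed-state genes, 5 were lower, with Lefty2 at −4.97 and Nodal at −3.38, Sox3 was higher at 2.39, and 7 did not pass (6 lower and 1 higher over the list alone). Their median was −1.83 (camera adjusted p = 0.0117, and adjusted p = 0.424 with an estimated correlation). The 11 trophoblast genes had 3 lower members, Krt8, Krt18 and Tfap2c, and 8 that did not pass (4 lower over the list alone), with a median of −0.30 (camera adjusted p = 0.0264, and adjusted p = 0.424 with an estimated correlation). Krt8 and Krt18 are also in the epithelial list, and 4 of the 11 genes were shared with other lists, so this call is not separate from that of epithelial genes. Regulators of epithelial-mesenchymal transition had 4 of 11 higher, Cdh2, Tgfb2 (2.10), Tgfbr2 (2.60) and Zeb1 (2.58), while Tgfb1 (−0.60) was lower and 6 did not pass (5 higher and 1 lower over the list alone). This list passed narrowly at a median of 0.78 (camera adjusted p = 0.0498, and adjusted p = 0.613 with an estimated correlation). Without the OKSM iNSC array it did not pass (adjusted p = 0.269), nor did trophoblast genes (adjusted p = 0.0845).

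Among metabolic, signalling and cell cycle lists, 4 passed camera in iNSC. Of 18 glycolysis genes, 7 were lower, including Slc2a3 (−3.50), Slc16a3 (−3.39) and Hk2 (−2.93), 2 were higher, Aldoc (0.84) and Pfkm (0.76), and 9 did not pass (15 lower and 2 higher over the list alone). The glycolysis median was −0.71 (camera adjusted p = 1.96e-04, and adjusted p = 0.424 with an estimated correlation). The list of Notch and Hedgehog targets also holds ligands and other pathway genes, such as Dll1, Smo and Gli3, which were among its higher members. Of its 18 measured genes, 7 were higher, with Hey1 at 3.38 and Dll1 at 2.45, Gli1 was lower at −3.39, and 10 did not pass (9 higher and 2 lower over the list alone). Their median was 0.66 (camera adjusted p = 0.00279, adjusted p = 0.613 with an estimated correlation, and adjusted p = 0.0602 without the OKSM iNSC array). Of 21 cell cycle genes only Ccne1 passed, lower by 1.23, and 20 did not (1 lower over the list alone), while the list median was −0.89 (camera adjusted p = 0.00200, and adjusted p = 0.709 with an estimated correlation). The cell cycle median was −0.60 in the OKSM and −1.14 in the BKSM line, and the list did not pass with fry (adjusted p = 0.141). Among 16 ribosomal and housekeeping genes, 6 were lower, including Rps18 (−0.72) and Tbp (−0.62), and 10 did not pass (12 lower and 2 higher over the list alone), at a median of −0.51 (camera adjusted p = 0.00439, and adjusted p = 0.687 with an estimated correlation).

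The remaining 18 lists did not pass camera in iNSC against iPSC, although single members did. Extracellular matrix and adhesion had 11 of 28 higher, such as Itgb8 (5.71) and Ncam1 (2.81), and 2 lower (11 and 3 over the list alone; camera adjusted p = 0.0876). DNA methylation and demethylation had 4 of 9 lower, with Tet1 at −3.90 and Dnmt3b at −2.76, and 2 higher, with Tet3 at 2.15 (5 and 2 over the list alone; camera adjusted p = 0.0587). Stress response had 5 of 20 higher, such as Fos (2.34), and 2 lower (5 and 3 over the list alone). Cell cycle inhibitors and p53 targets had 4 of 21 higher, with Cdkn2c at 4.43, and 1 lower (5 and 3 over the list alone). This list also holds the D-type cyclins, which promote the cell cycle, and Ccnd1 and Ccnd2 were among its higher members. Oligodendrocyte lineage had 4 of 15 higher, Olig1, Olig2, Cnp and Lhfpl3, and Myrf lower (4 and 1 over the list alone). Neuron had 1 of 24 higher, Map2 at 3.77, and 4 lower, with Stmn2 at −5.12 (1 and 4 over the list alone). Imprinted genes had 4 of 25 higher, such as Mest (1.96), and 2 lower, with Phlda2 at −5.31 (4 and 4 over the list alone). Cholesterol and fatty acid synthesis had 3 of 17 higher, with Hmgcs1 at 0.74, and Acly lower (3 and 1 over the list alone).

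Few members passed in the other lists of iNSC against iPSC. Klf4, Mycn (−2.88) and Pou5f1 were lower among 8 reprogramming factors (4 lower and 1 higher over the list alone), while Myc (1.28), Sox2 (−0.69), Pou3f4 (2.96), Mycl (0.28) and Tcf3 (0.02) did not pass. Interferon and antigen presentation had B2m (2.17) higher and 3 of 22 lower, with Ifitm3 at −0.63 (1 and 2 over the list alone). Forebrain patterning had Emx2 (2.68) and Lhx2 (1.91) higher among 17 (2 over the list alone). Midbrain and hindbrain patterning had Egr2 (2.16) and En2 (1.93) higher and Pax8 (−0.30) lower among 19 (2 and 1 over the list alone). Of 23 fibroblast and mesenchyme genes only Prrx1, a limb and mesenchyme homeobox gene, passed, higher by 2.96 (1 over the list alone). Hoxc13 was the only 1 of 36 Hox genes to pass (−1.70; 0 over the list alone). Dab2 (1.61) was higher and Eomes (−1.79) and Tbx6 (−0.49) were lower among 17 endoderm and mesoderm genes (1 lower over the list alone). Tek (−0.84) was lower among 13 microglia and endothelium genes, and Rlim (−0.68) was lower among 7 X inactivation and Y-linked genes (1 lower over the list alone in each). Among 16 liver and muscle genes, which belong to tissues not studied, Acta1 (−1.50), Actn3 (−1.97) and Mylpf (−2.56) were lower (3 over the list alone). Without either iPSC array 0 genes passed in this comparison, without the OKSM iNSC array 1398 were higher and 1544 lower, and without the BKSM iNSC array 990 were higher and 968 lower.

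**Figure D2:**
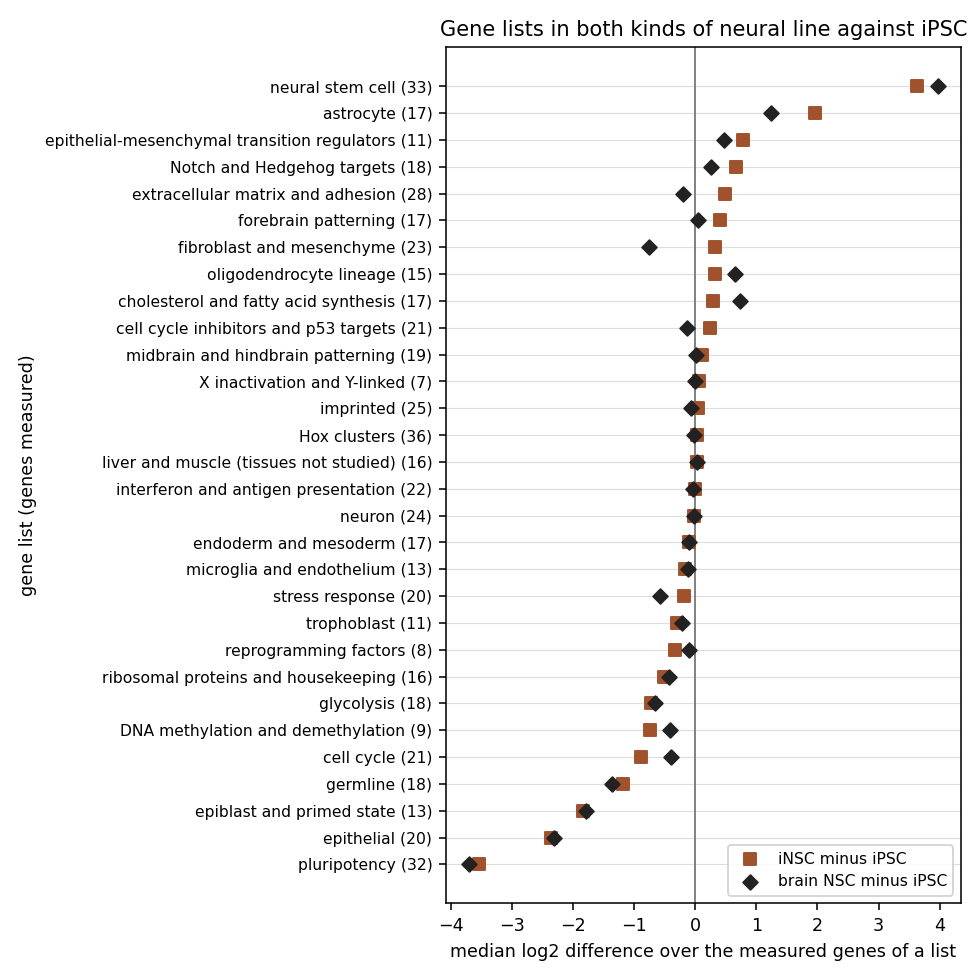
Median log2 difference of the measured genes of each list, for iNSC against iPSC (squares) and brain NSC against iPSC (diamonds). Brain NSC was measured on 1 array.

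In brain NSC against iPSC, too, pluripotency genes fell and neural stem cell genes rose. Ptprz1 rose to 11.88 in brain NSC from 3.70 ± 0.11 (SD, n = 2), at least 111-fold over background (limma adjusted p = 0.00942), and Olig2 rose to 11.65, at least 95.1-fold over background (adjusted p = 0.0128). Tdgf1 fell to 4.58 (adjusted p = 0.0194) and Nr0b1 to 4.56 (adjusted p = 0.0107), both under background, from iPSC levels 149.8-fold and 98.2-fold over it. With limma, 1975 genes were higher and 2006 lower, 17.9% of those tested, of which 1197 and 1146 by at least 2-fold. The lowest adjusted p, 0.00942, was again shared by 87 genes, among them Kitl at a log2 difference of 5.60.

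Other rule-named genes higher in brain NSC were Ednrb (7.15), Slc6a11 (7.11, a GABA transporter of astrocytes), Timp4 (6.98), Gpm6a (6.69), Hepacam (6.66, a glial cell adhesion molecule), Olig1 (6.55), Gpm6b (6.46) and Cd93 (6.43). Cd93 read 11.26 in brain NSC and 6.52 and 5.41 in the OKSM and BKSM iNSC lines. Lower genes were Fbxo15 (−6.95), Slc38a4 (−6.84, an imprinted amino acid transporter), Zfp981 (−6.70), Utf1 (−6.56), Zfp640 (−6.42), Kcnma1 (−6.25), Stmn2 (−6.19) and Zscan4e (−6.10). Kcnma1 did not pass with the mean of its probe sets (−1.52, adjusted p = 0.0774), nor Ednrb with every probe set tested (adjusted p = 0.0555), nor Cd93 with iNSC and brain NSC as 1 neural group (2.90, adjusted p = 0.393). Without either iNSC array Timp4 (adjusted p = 0.0651) and Hepacam (0.0543) did not pass. The dimmer mean lay under background for 13 of the 20 genes named by rule.

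The pluripotency list had 27 of 32 genes lower in brain NSC and 5 that did not pass (28 lower over the list alone), with a median of −3.69, and Nanog fell by 6.02 (camera adjusted p = 7.81e-16, and adjusted p = 0.188 with an estimated correlation). Neural stem cell genes had 22 of 33 higher and 11 that did not pass (26 over the list alone), with a median of 3.97, and Nes rose by 3.40 and Sox9 by 4.60 (camera adjusted p = 2.41e-13, and adjusted p = 0.188 with an estimated correlation). Of 20 epithelial genes 14 were lower, with Cdh1 at −5.54 and Epcam at −5.72 (17 over the list alone; median −2.30; camera adjusted p = 4.42e-10, and adjusted p = 0.188 with an estimated correlation). Of 18 germline genes 10 were lower, with Mael at −5.89 (13 over the list alone; median −1.36; camera adjusted p = 1.40e-07, and adjusted p = 0.407 with an estimated correlation). Of 17 astrocyte genes 6 were higher, with Mlc1 at 5.48 and Aldh1l1 at 3.12, and 11 did not pass (12 higher and 2 lower over the list alone; median 1.24; camera adjusted p = 6.20e-04, and adjusted p = 0.407 with an estimated correlation). Gfap, the astrocyte intermediate filament, did not pass in brain NSC at 0.55 (adjusted p = 0.698).

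Cholesterol and fatty acid synthesis had 4 of 17 genes higher in brain NSC, Hmgcs1 (1.34), Scd1 (1.08), Fasn (0.61) and Sc5d (1.86), with 13 not passing (6 over the list alone; median 0.74; camera adjusted p = 4.27e-04, and adjusted p = 0.748 with an estimated correlation). Glycolysis had 4 of 18 lower, with Hk2 at −2.58 and Slc16a3 at −2.19 (8 lower and 2 higher over the list alone; median −0.65; camera adjusted p = 9.72e-04, and adjusted p = 0.407 with an estimated correlation). Epiblast genes had 3 of 13 lower, with Lefty2 at −5.07, and Sox3 higher at 2.65 (5 and 1 over the list alone; median −1.79; camera adjusted p = 0.0120, and adjusted p = 0.407 with an estimated correlation). Trophoblast genes had 4 of 11 lower, among them Krt8 (−2.56) and Krt18, which are also in the epithelial list (4 over the list alone; median −0.21; camera adjusted p = 0.0382, and adjusted p = 0.407 with an estimated correlation). Stress response had 3 of 20 lower, with Ier3 at −2.08, and 2 higher, Egr1 (1.53) and Fosb (1.28) (5 and 4 over the list alone; median −0.58; camera adjusted p = 0.0382, and adjusted p = 0.407 with an estimated correlation). Notch and Hedgehog targets had 6 of 18 higher, with the ligand gene Dll1 at 3.14 and Hey1 at 3.04, and Gli1 lower at −3.15 (6 and 1 over the list alone; median 0.27; camera adjusted p = 0.0438, and adjusted p = 0.748 with an estimated correlation). DNA methylation and demethylation had 3 of 9 lower, with Dnmt3l at −4.41 and Tet1 at −3.18, and Tet3 higher at 2.77 (4 and 1 over the list alone; median −0.42; camera adjusted p = 0.0438, and adjusted p = 0.533 with an estimated correlation). Leaving out 1 array ended the call of trophoblast genes in each case (adjusted p from 0.0688 to 0.0917) and of Notch and Hedgehog targets in each case (0.0664 to 0.127). It ended that of DNA methylation genes without either iPSC array (0.177 without clone 2 and 0.0922 without clone 7) and of stress response without iPSC clone 7 (0.0511). Ribosomal and housekeeping genes had 6 of 16 lower, with Rps18 at −0.87 (7 lower and 1 higher over the list alone; median −0.42; camera adjusted p = 0.00937, and adjusted p = 0.748 with an estimated correlation).

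The other 17 lists did not pass camera in brain NSC against iPSC. Cell cycle had only Ccne1 (−1.32) lower among 21 (1 over the list alone; camera adjusted p = 0.0941). Extracellular matrix and adhesion had 6 of 28 higher, with Itgb8 at 6.12, and 6 lower, with Timp1 at −3.03 (8 and 6 over the list alone). Interferon and antigen presentation had 3 of 22 higher, with B2m at 1.73, and 5 lower, with Ifitm3 at −4.14 (3 and 5 over the list alone). Cell cycle inhibitors and p53 targets had 3 of 21 higher, Cdkn2c and the D-type cyclins Ccnd1 and Ccnd2 (4.22), and 3 lower, with Perp at −3.59 (3 and 5 over the list alone). Neuron had 4 of 24 higher, with Map2 at 4.24, and 3 lower (5 and 4 over the list alone). Oligodendrocyte lineage had 5 of 15 higher, with Cspg4 at 1.27, and Myrf lower (5 and 1 over the list alone). Imprinted genes had Mest (1.76) higher and 5 of 25 lower, with Phlda2 at −5.48 (3 and 5 over the list alone). Epithelial-mesenchymal transition regulators had 3 of 11 higher, with Zeb1 at 3.14, and Tgfb1 lower at −2.61 (4 and 1 over the list alone). Klf4 (−3.56), Mycn (−3.20) and Pou5f1 (−1.81) were lower among 8 reprogramming factors, while Sox2 (−0.23), Myc (1.18), Pou3f4 (3.97), Mycl (1.03) and Tcf3 (0.03) did not pass (3 lower and 1 higher over the list alone).

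Acta1, Actn3 and Mylpf (−2.58) were lower in brain NSC among 16 liver and muscle genes (3 over the list alone), and Rlim (−1.02) was lower among 7 X inactivation and Y-linked genes (1 over the list alone). Emx2 (2.51) and Lhx2 (2.11) were higher among 17 forebrain patterning genes (2 over the list alone). Members that passed over all genes but not over their list alone were Fn1 (−2.87) among 23 fibroblast and mesenchyme genes, Eomes (−1.51) among 17 endoderm and mesoderm genes and Tek (−0.64) among 13 microglia and endothelium genes. The same held for Hoxc13 (−1.45) among 36 Hox genes and for Egr2 (1.66) and Pax8 (−0.42) among 19 midbrain and hindbrain patterning genes. Brain NSC had 1 array, so its p-values assume that it varied like the other lines. Without either iPSC array 0 genes passed, and without either iNSC array 1120 were higher and 1183 lower.

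Both comparisons used the same 2 iPSC arrays and called largely the same genes. Of the genes called, 1528 were higher in both and 1736 lower in both, against 188 and 224 had the lists been independent. Kitl, Ptprz1 and Olig2 were among those higher in both, and Cdh1, Nanog and Tdgf1 among those lower in both. The log2 differences correlated at 0.918 across genes, compared with 0.409 in 100 simulations without any group difference, in which the shared arrays alone produced the correlation. Part of the excess over independence may therefore come from the shared arrays, while the covariance of 0.867 stood against 0.0192 in the simulations, a difference of 0.847. Taking each of the 3981 genes called between brain NSC and iPSC from 0 at iPSC to 1 at brain NSC, the median position was 0.887 (quartiles 0.652 to 1.06) for the OKSM iNSC line and 0.880 (quartiles 0.628 to 1.06) for the BKSM iNSC line. The OKSM line lay closer to brain NSC than to iPSC for 82.6% of these genes and the BKSM line for 81.9%. Simulated arrays without group differences gave a median position of 0.333.

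In iNSC against brain NSC, limma called 0 genes higher and 0 lower at adjusted p under 0.05. At unadjusted p under 0.05, 1184 were higher and 1757 lower, and the lowest adjusted p, 0.0563, was shared by 8 genes. Dlgap1, a postsynaptic scaffold gene among them, read 8.17 in brain NSC and the same value, 5.53, on both iNSC arrays. Under other settings of the limma model, 9 higher and 4 lower genes passed after quantile normalization again, 7 and 4 after median centring, 8 and 4 after cyclic loess, and 8 and 2 among genes with a mean above the median. Further settings gave 6 and 3 among genes above background and, chosen after the data were seen, 14 and 5 without genes at the same value on 3 or more arrays. Il33, which encodes an alarmin cytokine of glia, read 6.17 in brain NSC and 9.34 ± 0.04 in iNSC, and Osmr, the oncostatin M receptor, read 5.48 and 9.32 ± 0.03. Anxa2 (3.53), Ifitm3 (3.51), Shisa3 (2.91) and Tbx15 (2.43) were the other genes that passed as higher under 6 settings. Brinp3 (−3.54) and Rgcc (−2.28) passed as lower under 6 settings. Anxa2 read 5.79 in brain NSC, but 9.41 and 9.31 in iPSC beside 9.32 in both iNSC lines. For Ifitm3, Rgcc and Brinp3, too, iNSC lay nearer to iPSC than to brain NSC, so brain NSC was the sample apart. All genes named from these settings were chosen after their values were seen, and none passed under the primary settings. Fits without 1 iPSC or iNSC array left a single array in that group, too few to tell anything about these genes.

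At the level of lists, no member passed over all genes in iNSC against brain NSC. Neural stem cell genes had a median of −0.04 (0 of 33 passed; camera adjusted p = 0.707), with Nes at −0.07 and Fabp7 at 0.08, and pluripotency genes had a median of 0.19 (0 of 32; 0.0832). The pluripotency median was 0.28 in the BKSM line, above all of 10000 random lists of similar intensity, and −0.01 in the OKSM line. Germline genes had the same place between iPSC clones 2 and 7, at a median of 0.19, so such a place also occurs between like lines. Extracellular matrix and adhesion genes were higher in iNSC at a median of 0.76 among 28 (1 over the list alone; camera adjusted p = 2.35e-06, and adjusted p = 0.644 with an estimated correlation). Fibroblast and mesenchyme genes had a median of 1.48 among 23 (0 over the list alone; camera adjusted p = 3.77e-04, and adjusted p = 0.811 with an estimated correlation), with Prrx1 at 2.63. Most of this came from 1 array, since the median was 2.71 in the OKSM line and 0.14 in the BKSM line. Cell cycle inhibitors and p53 targets had a median of 0.38 among 21, 0.24 in the OKSM and 0.47 in the BKSM line (0 over the list alone; camera adjusted p = 2.35e-04, and adjusted p = 0.644 with an estimated correlation). D-type cyclins are part of this list, so its median does not describe inhibitors alone. Stress response had a median of 0.27 among 20, with Ier3 at 3.00 (1 over the list alone; camera adjusted p = 6.91e-04, and adjusted p = 0.644 with an estimated correlation). Against iPSC the stress response median was −0.19 in iNSC and −0.58 in brain NSC, so iNSC did not lie above iPSC by this median. Interferon and antigen presentation genes had a median of 0.15 among 22 (3 higher and 1 lower over the list alone; camera adjusted p = 0.00287, and adjusted p = 0.644 with an estimated correlation). Imprinted genes passed narrowly at a median of 0.17 among 25 (0 over the list alone; camera adjusted p = 0.0482, adjusted p = 0.644 with an estimated correlation, and adjusted p = 0.299 without the OKSM array). Cholesterol and fatty acid synthesis genes were lower, at a median of −0.54 among 17, with Hmgcs1 at −0.60 (0 over the list alone; camera adjusted p = 2.35e-06, and adjusted p = 0.644 with an estimated correlation). With fry only extracellular matrix and adhesion passed (adjusted p = 7.95e-04).

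The other 21 lists did not pass in iNSC against brain NSC, and 0 members passed over all genes in any of them. Astrocyte genes (17) had a median of −0.04 (0.15 in the OKSM and −0.18 in the BKSM line) with 1 higher and 1 lower over the list alone, and Gfap, at 5.85 in brain NSC and 9.73 ± 0.93 (SD, n = 2) in iNSC, did not pass (3.88, limma adjusted p = 0.255). Over the list alone neuron genes (24) had 3 lower with a median of −0.15, oligodendrocyte genes (15) had 1 lower, and midbrain and hindbrain patterning genes (19) had 1 higher, with En2 at 2.63 (adjusted p = 0.169). Epithelial-mesenchymal transition regulators (11) had 2 higher over the list alone with a median of 0.33 (0.54 in the OKSM and 0.29 in the BKSM line), and DNA methylation genes (9) had 1 higher and 2 lower with a median of −0.22 (−0.01 and −0.30). With 0 genes over the list alone, cell cycle (21) had a median of −0.38, which came mostly from the BKSM line (−0.71, against −0.07 in the OKSM line), and glycolysis (18) of −0.21 (−0.30 in the OKSM and −0.16 in the BKSM line). Medians of both lines together lay between −0.10 and 0.10, also with 0 over the list alone, for epithelial (20), epiblast (13), germline (18), trophoblast (11), endoderm and mesoderm (17), microglia and endothelium (13) and forebrain patterning (17) genes. The reprogramming factors read Pou5f1 0.45, Sox2 −0.46, Klf4 0.75, Myc 0.10, Pou3f4 −1.01, Mycn 0.33, Mycl −0.75 and Tcf3 −0.01, and their median (8 genes) lay in the same range. So did those of Hox genes (36), X inactivation and Y-linked genes (7), Notch and Hedgehog targets (18), ribosomal and housekeeping genes (16) and liver and muscle genes (16). Among these, the lines went opposite ways for Notch and Hedgehog targets (0.18 in the OKSM and −0.11 in the BKSM line), Hox genes (−0.05 and 0.18) and X inactivation and Y-linked genes (0.12 and −0.10), for example. In all 3 comparisons together, median, mean and camera direction differed in sign for 18 of the 58 list tests that did not pass and for 0 of the 32 that did. Hox genes in iNSC against iPSC and astrocyte genes in iNSC against brain NSC were such lists.

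Both iNSC lines were then set against brain NSC separately, without a test. Of 14991 genes, 509 were at least 2-fold higher in the OKSM line and 517 in the BKSM line, with 238 in both. For lower genes the counts were 223 and 343, with 122 in both. Independent lines would share 17.6 and 5.10, and simulations in which the lines shared 1 brain NSC array gave 46.5 and 46, so part of the excess may come from that array. Lcn2, the secreted lipocalin of reactive astrocytes, chosen after its values were seen, was among the shared higher genes, at 5.74 in brain NSC, 8.96 in the OKSM line and 10.75 in the BKSM line. Timp1, an inhibitor of matrix proteases, was another, at 6.92, 9.15 and 9.84, with 9.95 ± 0.08 (SD, n = 2) in iPSC.

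The OKSM and BKSM iNSC lines differed from each other in 657 genes by at least 2-fold, 387 higher and 270 lower in the OKSM line, and in 163 by at least 4-fold. This pair had 1 array per line and no replicate check. Genes of mesenchymal cells were higher in the OKSM line. The small proteoglycan genes Bgn (12.11 in OKSM, 5.87 in BKSM), Dcn (11.53, 5.49) and Lum (8.21, 3.68) were among them. So were Postn, which encodes the matrix protein periostin (11.25, 5.99), Apod (11.47, 5.87) and Inmt (8.98, 4.72). Xist, the RNA of the inactive X chromosome, had the widest difference, 11.48 against 4.78, while the Y-linked genes Kdm5d (3.53, 7.63), Uty (4.34, 8.37) and Eif2s3y (4.92, 8.93) were high in the BKSM line. Cassette, line and sex of the cells therefore could not be told apart in this pair. Also higher in the OKSM line were Six3os1 (9.03, 4.56), Kcnj10 (11.21, 6.92) and Fndc3c1 (9.23, 4.95). The BKSM line had the higher values of Hoxa2 (4.90 in OKSM, 9.88 in BKSM), Hoxa5 (4.78, 9.56), Steap4 (5.09, 9.78) and Mme (6.25, 10.86). It also had those of Clic5 (5.27, 9.19), Chrm3 (5.11, 8.95) and Pcdhb6 (6.61, 10.24).

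**Figure D3:**
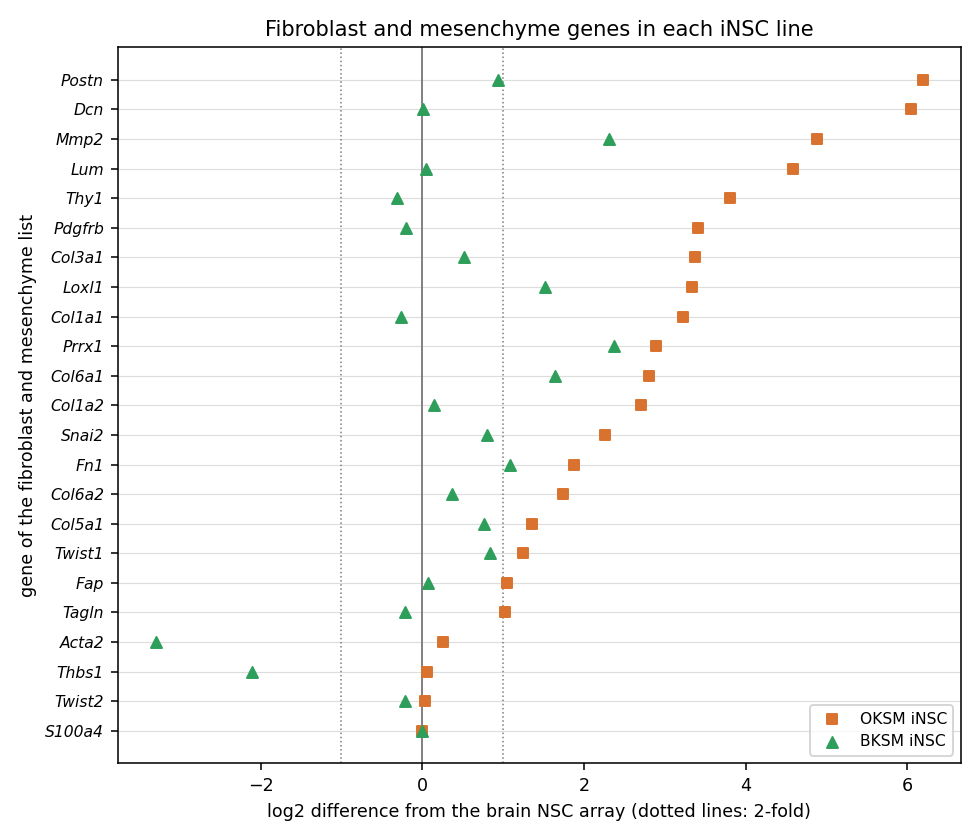
Log2 difference from brain NSC of 23 fibroblast and mesenchyme genes in the OKSM (squares) and BKSM (triangles) iNSC lines. Dotted lines mark 2-fold, and each point compares 1 array with 1 array.

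Among the lists, 16 of 23 fibroblast and mesenchyme genes were at least 2-fold higher in the OKSM than in the BKSM line, and 0 were lower (median 1.82, above all of 10000 random lists of similar intensity). Against brain NSC 19 of the 23 were at least 2-fold higher in the OKSM line and 5 in the BKSM line. Of 36 Hox genes, 9 were at least 2-fold higher in the BKSM line than in both the OKSM line and brain NSC. They were Hoxa2, Hoxa4 (9.13 in BKSM), Hoxa5, Hoxa6 (7.20), Hoxb2 (7.66), Hoxb3 (9.20), Hoxb4 (6.61), Hoxb8 (7.27) and Hoxd8 (7.30). All 9 belonged to paralogue groups 1 to 8, with 21 measured genes, and 0 of 15 measured genes of groups 9 to 13 differed in this way. The cut at group 8, the highest raised group, was chosen after the values were seen, so these counts are a description only. No Hoxc gene was among the 9. Forebrain patterning genes had 5 of 17 higher in the OKSM line, with Otx2 at 8.67 against 5.48 and Six3 at 8.03 against 6.15. Imprinted genes had 7 of 25 higher and 1 lower in the OKSM line, with Igf2 at 9.86 against 6.15 and Dlk1 at 8.32 against 6.48. Astrocyte genes had 5 of 17 higher in the OKSM line, oligodendrocyte lineage genes 2 of 15, with Pdgfra at 9.19 against 5.96, and midbrain and hindbrain patterning genes had 4 of 19 lower, with Pax3 at 5.38 against 7.10. The cell cycle median was 0.62 higher in the OKSM line, above all random lists. A place above all random lists was also seen between the iPSC clones, for germline genes at a median of 0.19.

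**Figure D4:**
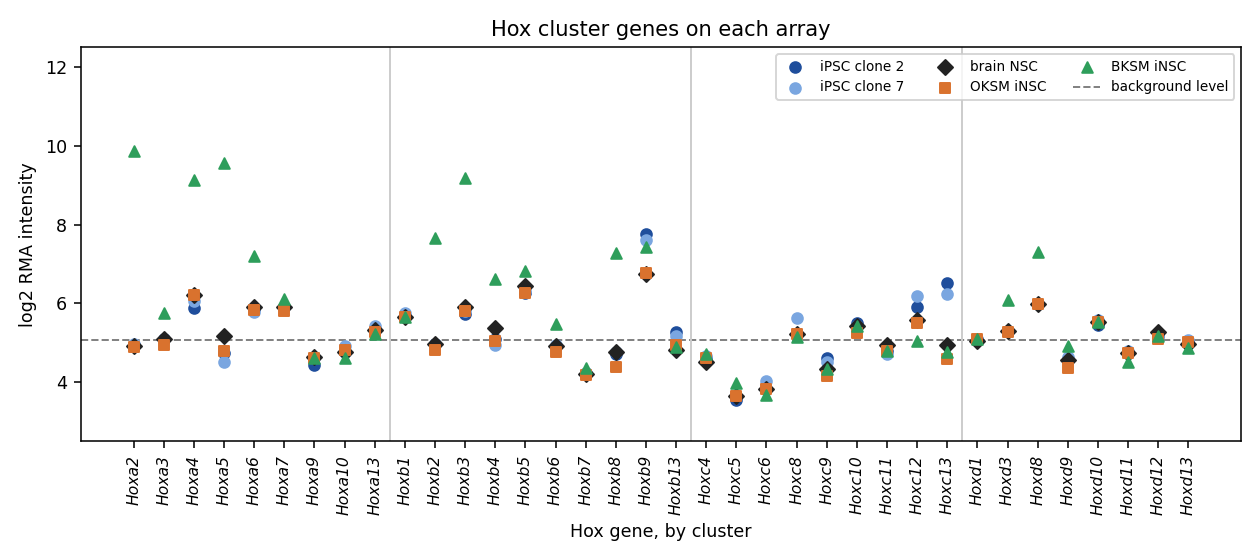
Log2 RMA intensity of 36 Hox genes by cluster on each of the 5 arrays, 1 point per array. The dashed line marks the background level, log2 5.08.

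The iPSC clones 2 and 7 differed by at least 2-fold in 19 genes, 5 higher and 14 lower in clone 2, and by at least 4-fold in 0. Pou5f1 read 7.89 in clone 2 and 7.76 in clone 7, Nanog 12.10 and 12.00, and Tdgf1 12.33 and 12.28. The Y-linked genes Uty (8.24 ± 0.15, SD, n = 2) and Eif2s3y (9.41 ± 0.07, SD, n = 2) were high in iPSC, and Kdm5d read 3.86 ± 0.15.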

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

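The genes below were looked at one by one only after the result was seen, and no new test was run on them.

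A total of 20 genes passed the limma threshold against iPSC in opposite directions in iNSC and in brain NSC, which stood out because the groups that were otherwise alike differed in sign. Of these, 18 were higher in iNSC and lower in brain NSC, and Tmem145 and Efs went the other way. The largest spans were those of Rps13, a ribosomal protein gene (log2 difference 3.18 in iNSC and −1.78 in brain NSC), Ier3, an immediate early gene (0.92 and −2.08), and Tbx15, a mesenchymal T-box gene (1.48 and −0.96). Fstl1 (1.33 and −0.98), Casp8 (0.90 and −1.09), Cavin1 (0.89 and −1.12) and Ndrg2 (0.46 and −1.30) followed. The difference itself, iNSC against brain NSC, was tested in the same model and passed for 0 of the 20 (limma adjusted p from 0.0563 to 0.166). Under alternative settings Tbx15 passed in 6 (adjusted p from 0.0312 to 0.0491), and Ier3 (0.0322) and Rps13 (0.0356) passed in 1, without genes at the same value on 3 or more arrays, a setting added after the data were seen. Brain NSC had 1 array, and Rps13 and Tbx15 read there under the background level of 5.08. Tspan17, Ilvbl, Erc1 and Olfr491 had the same value on both iPSC arrays, and the differences of some were small, such as Erc1 (0.18 and −0.24). Olfr491 lay under background on every array.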

How the results depend on the processing

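Alternatives fixed before the data were examined were run for gene and list counts, named genes, array correlations and positions, and 2 for each pair of single lines. None was run for the genes shared between comparisons or lines, or for percentiles among random lists. A further setting, leaving out genes at the same value on 3 or more arrays, was added after the data were seen. No result past a threshold reversed its sign. Calls against iPSC largely held under other scalings, where 4472 of the 4590 genes of iNSC against iPSC were called again after cyclic loess, and changed most when 1 array was left out. Under thresholds, at least 2-fold gave 1273 higher and 1249 lower (iNSC against iPSC) and 1197 and 1146 (brain NSC against iPSC), and adjusted p under 0.01 gave 255 and 303, and 65 and 59. Leaving out 1 array gave 0 to 1398 higher and 0 to 1544 lower in iNSC against iPSC, and 0 to 1120 and 0 to 1183 in brain NSC against iPSC. The 0 came from either iPSC array, which leaves only the iNSC pair to estimate spread. With iNSC and brain NSC as 1 neural group, brain NSC lower became 3100. In iNSC against brain NSC the main count was 0 in both directions. It became 9 higher and 4 lower (quantile normalization again), 7 and 4 (median centring), 8 and 4 (cyclic loess), 8 and 2 (mean above median), 6 and 3 (above background), and 14 and 5 (without genes at the same value). The largest counts thus came without genes at the same value. The mean of a gene's probe sets, every probe set tested, and limma with trend and robust options kept 0 and 0. Those 3 settings left genes at the same value largely in place, while the settings that gained calls rescaled the arrays or left out dim genes or genes at the same value. Whether genes at the same value account for the 0 of the primary settings was not tested further. Of gene lists, 4 Up and 8 Down, 4 and 9, and 6 and 1 passed in the 3 comparisons. With an estimated correlation, which rests on 2 residual degrees of freedom, 0 and 0 passed in each, also where the estimate lay under the preset. With fry, 7 Up and 13 Down, then 15 Down, then 1 Up and 0 Down passed. Testing lists among genes above background gave 3 Up and 8 Down, 3 and 7, and 5 and 1, and ended 5 calls. They were epithelial-mesenchymal transition regulators in iNSC against iPSC (adjusted p = 0.0676), DNA methylation (0.0964), Notch and Hedgehog targets (0.0595) and stress response (0.0837) in brain NSC against iPSC, and imprinted genes in iNSC against brain NSC (0.0528). Leaving out 1 array gave 3 to 8 lists Up in iNSC against iPSC and 1 to 2 Down in iNSC against brain NSC. Correlations among bright genes only (mean above median) were 0.994 between iPSC clones, 0.932 between iNSC and brain NSC and 0.651 between neural and iPSC arrays, and Spearman gave 0.983 for iNSC with brain NSC and 0.919 for neural with iPSC arrays. The position of the OKSM and BKSM lines was 0.937 and 0.933 for genes with a log2 difference of at least 2, and 0.895 and 0.890 after cyclic loess. Among named genes 541 checks kept the call and 117 were weaker, and among lists 165 and 59. For the genes named between the OKSM and BKSM lines 39 checks kept the difference and 1 moved, with the mean of a gene's probe sets. No paired analysis was possible because no arrays shared a culture or donor in the labels. RMA values carry no detection call, so dim genes were limited by the background level used here.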

Other observations

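The comparisons of single lines below, the list of reactive genes and the tests of explanations were chosen only after the result was seen.

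Some genes that astrocytes switch on after injury read higher in both iNSC lines than in brain NSC. Of 13 genes of a published pan-reactive set, all measured and chosen after some of its members had been seen to be high, 8 were at least 2-fold above brain NSC in both lines. Steap4 and Cxcl10 were so only in the BKSM line and Vim, Aspg and Cd44 in neither, and the 13 had a median log2 difference of 2.23 in the OKSM line and 2.91 in the BKSM line. Serpina3n, a secreted protease inhibitor, read 5.82 in brain NSC, 9.13 in the OKSM line and 11.78 in the BKSM line, with 4.82 ± 0.16 (SD, n = 2) in iPSC. S1pr3, a sphingosine phosphate receptor, read 6.17, 11.25 and 8.16, with 6.65 ± 0.22 in iPSC. Hspb1, a small heat shock protein, read 4.88, 7.44 and 6.89, but 10.89 ± 0.19 in iPSC, and Timp1 read 6.92, 9.15 and 9.84, but 9.95 ± 0.08 in iPSC, so iPSC read above both iNSC lines for these genes and brain NSC was the low sample. None passed limma over all genes (adjusted p from 0.0648 to 0.851), while Osmr passed under 6 alternative settings (0.0250 to 0.0491).

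Nuclear receptor gene Nr2f2 read 5.31 in brain NSC and 8.74 and 8.60 in the OKSM and BKSM iNSC lines. Rps13 read 4.34 in brain NSC, 6.05 and 6.21 in iPSC and 9.07 and 9.55 in iNSC, a log2 difference of 4.96 from brain NSC where 59 other ribosomal protein genes lay between −0.22 and 0.48, and its brain NSC value lay under the background level of 5.08. Y-linked Kdm5d read 3.76 and 3.97 in iPSC and 8.01 in brain NSC, while Uty read 8.13 and 8.35 in the same iPSC arrays. Xist was high only in the OKSM iNSC line, at 11.48, where Uty (4.34) and Eif2s3y (4.92) lay under background. Both Y-linked genes were high on every other array, with 8.37 and 8.93 in the BKSM iNSC line and 8.02 and 8.64 in brain NSC. By these genes the OKSM line read as female and the others as male, although the labels give both sexes for every sample.

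The high Hox genes of the BKSM iNSC line were weighed first. Under cyclic loess 9 Hox genes were still at least 2-fold higher than in the OKSM line. The array medians were already alike (log2 5.39 in the OKSM and 5.40 in the BKSM line). Cyclic loess could therefore hardly change such differences, and this check decides nothing about the scaling of the arrays. That the BKSM cassette raises these genes in every cell state was argued against by a median of −0.0910 for the same Hox genes in BKSM iPSC minus brain NSC. This value covers only the iPSC state and cannot decide about the cassette in neural cells. Fibroblasts in the culture, as the whole source, were argued against by the fibroblast list fixed beforehand, whose median was 0.141 (SD of the 23 members 1.24) in BKSM iNSC minus brain NSC beside 2.68 for the 9 Hox genes, with Dcn at 0.01 and Col1a1 at −0.26, although 5 members were at least 2-fold higher. Other mesodermal cells, the source tissue and the cassette during conversion or in neural cells were not tested and stay open with 1 line.

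Mesenchymal genes of the OKSM iNSC line were weighed next. Under cyclic loess 16 of 23 list members were still at least 2-fold higher than in the BKSM line, but this check of the scaling has the same limit as for the Hox genes. Fibroblasts in the culture cannot be told apart from expression in the neural cells, because 19 of the 23 members at least 2-fold above brain NSC are predicted by both.

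For the reactive astrocyte genes of both iNSC lines, weighed last, 8 were still at least 2-fold above brain NSC in both lines under cyclic loess. This check of the scaling has the same limit as for the Hox genes. Fibroblasts in the culture of the BKSM line were argued against by the fibroblast list median of 0.141 (SD of members 1.24) beside 2.91 for the reactive genes, although the extracellular matrix and adhesion list had 12 of 28 members at least 2-fold higher there (median 0.80). Fibroblasts in the culture of the OKSM line cannot be told apart from expression in the neural cells, since 19 of 23 fibroblast list members were at least 2-fold above brain NSC. An unusual brain NSC line cannot be told apart from a change in the iNSC lines, since 238 genes were at least 2-fold higher in both and only 1 brain NSC line was measured. Culture conditions and passage were not tested.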
